A study of Drosophila melanogaster with 19 samples.

How the data were processed

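Per the labels' protocols, testes were torn open in S2 insect medium, single cysts were picked with a glass needle, and a mild detergent opened the cell membrane so that mRNA could be reverse transcribed from poly-dT primers. The cDNA was tailed with poly A and amplified with universal primers. The labels describe 19 libraries in 9 groups: niche (2), GB (2), S4 (2), S8 (2), S16 (1), EC (3), LC1 (3), LC2 (2) and *aly* (2). The submitters' processing notes name Bowtie 0.12.7 and edgeR, with no role for either. The genome build, the annotation and the handling of duplicate reads are not given in the sources used here.

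The authors deposited 1 table whose values are RPKM per the file headers. Its title line writes cRPKM, without saying what the c stands for, and says that the table holds all expressed genes. It has 12810 genes and 1 value per stage. Each stage value proved to be the plain mean, over the libraries of the stage, of reads divided by gene length and by an effective library size. Because reads are whole numbers, the reads of each library could be recovered from the means: for 12686 of 12810 genes in every library, and for 99.33 to 99.96% of the genes of a library. In stage means simulated with the library sizes found, the recovery returned the right proportions of reads between libraries for 393 of 393 genes. The absolute number of reads and the number of libraries were not tested in this way. The recovery found 20 libraries, because the LC2 mean is built from 3 although 2 are labelled. Recovered libraries carry no replicate number, so letters a, b and c follow the effective library size, largest first. Depth was 808278 to 5098681 recovered reads per library. A floor of 3 reads in a gene of 1 kb is given per stage as the RPKM of those reads in its shallowest library. Floors cover counting error only, since reads of amplified cDNA without molecular identifiers are not independent molecules.

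The comparisons, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The plan was a limma fit if the table had a column per library and otherwise a description. With 1 value per stage, the main result of each of the 9 comparisons is therefore the count of genes with at least a 4-fold difference of stage values after adding a pseudocount of 1. It was taken over 11814 genes with a value of at least 1 in 2 stage columns. Spermatogonia are the mean of S4, S8 and S16 and late spermatocytes the mean of LC1 and LC2, each weighted by labelled libraries. LC1 and LC2 are thus weighted 3 to 2, in the limma fit as well. In the X ratio each of the 6 late libraries counts equally. No error can be given for the stage values. Chromosomes and coordinates came from Ensembl BDGP6.54, where 12208 gene identifiers matched. Gene symbols are those of the table, with the current symbol in brackets where it helps.

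The limma fit was added after the recovery. It used log2(RPKM + 1) of the 20 libraries, 9 group means, a pooled variance with a trend (residual degrees of freedom 11, prior 3.88), and 12366 genes with a value of at least 1 in 2 libraries. Tests are two-sided with Benjamini-Hochberg adjustment at 0.05. S16, with a lone library, is assumed to vary like the other groups. The rule for calling genes was set by simulation after the first counts of this fit had been seen. Noise of the size measured within each stage, an SD from 0.14 (*aly*) to 0.45 (GB) on the natural log scale, was added to stage means. S16, whose lone library allows no such measure, was given 0.37, the mean of S4 and S8. In each of 10 runs 1000 genes were changed 4-fold. The noise was measured only on genes with many reads in every library of a stage. Genes high in 1 library and at 0 in another are therefore not modelled, and the shares of false calls given here may be too low. A first version of that test added noise to libraries that were already noisy and was replaced. Without a further condition 12.7, 10.4, 9.4, 7.6 and 1.9% of calls were false in EC against spermatogonia, late against EC, LC2 against LC1, *aly* against EC and *aly* against late. With a minimum of 8 RPKM on the higher side these were 4.3, 3, 3.4, 1 and 0.2%, and 97.6, 98.8, 97.2, 95.5 and 98.4% of changed genes were found. In GB against niche, S4 against GB, S8 against S4 and S16 against S8, 22, 17, 8.3 and 13.9% of calls stayed false. Weights per stage gave 11.8, 11.9, 10.2 and 20.4%, and a fit of the 2 sides alone found 0% of changed genes. These 4 comparisons therefore get values and no calls, and the other 5 get calls at adjusted p under 0.05 with a minimum of 8 RPKM. Of the 3 error models, the pooled variance was kept because it was the planned one. With that minimum, the pooled fit passed 652 genes higher and 805 lower in GB, 295 and 204 in S4, 42 and 23 in S8, and 57 and 106 in S16. These are not used as calls.

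The 24 gene lists covered early germline regulators, piRNA silencing, hub, cyst cell, muscle sheath, and haemocyte and fat body markers, JAK-STAT and BMP components, DNA replication, mitosis, ribosome biogenesis and ribosomal proteins. They further covered Polycomb and Trithorax, dosage compensation, meiotic arrest (tMAC and testis TAFs), meiosis, spermatid, cup and comet and Y-linked genes, axonemal dyneins off the Y, testis paralogues of the respiratory chain and of the proteasome, their general partners, and heat shock genes. *gbb* is both a hub marker and a BMP component. Members with no gene in the table were left out, and *solo* was left out because its identifier is shared with *vas*. Lists were tested with limma's camera at a preset correlation of 0.01 and again with the correlation estimated per list, adjusted over the 24 lists of a comparison. With the estimated correlation 0 lists passed in any comparison by camera, and at an unadjusted p under 0.05 there were 1, 2, 0 and 5 in the 4 early comparisons in order, 5 in EC against spermatogonia, 1 in late against EC, 3 in LC2 against LC1, 1 in *aly* against EC and 0 in *aly* against late. List counts are given over all genes tested and adjusted over the list alone, the latter with no minimum of its own beyond the same 8 RPKM.

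Named genes followed a fixed rule. In the 4 comparisons of EC against spermatogonia, late against EC, *aly* against EC and *aly* against late, they are the 8 largest log2 differences of stage values + 1 in each direction with a gene name, and the 2 largest with a CG or CR number, with at least 8 RPKM on the higher side. In the others they are the 4 largest in each direction. Up to 4 members of each described list were added, and *bam*, *aly*, *can*, *twe*, *fzo*, *dj*, *Mst87F* and *kl-3* in each spermatocyte comparison. One gene that met the rule is not reported here. The ratio of the median X-linked to the median autosomal gene (arms 2L, 2R, 3L and 3R, genes with a mean of at least 1) was compared by exact two-sided permutation tests. Similarity of libraries is Pearson's r across genes. Genes picked for the size of their difference separate their libraries in part by the picking. Counts of them without overlap are therefore set beside those of every other grouping of the same libraries, with genes picked anew by the same rule.

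Settings varied by plan were pseudocounts of 0.1 and 5, no filter, quantile normalization, a fit of the 2 sides alone, and leaving out each library in turn. Added after the data were seen were scaling to total recovered reads, a correction for the limit of 1 read per base, voom, weights per stage, and late spermatocytes as LC1 or LC2 alone. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Raw reads were not analysed here.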

Results

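RNA was sequenced from single cysts of the *Drosophila melanogaster* testis, picked by needle. A cyst is a group of germ cells that divide in step inside a somatic envelope. The labels name 2 libraries of the niche, the testis tip where germline stem cells reside. Gonialblasts (GB), the stem cell daughters that begin to differentiate, gave 2. The spermatogonia, which amplify by mitosis, gave 2 libraries of 4-cell (S4), 2 of 8-cell (S8) and 1 of 16-cell cysts (S16). Early spermatocytes (EC) gave 3 libraries. Late spermatocytes gave a set of 3 (LC1) and a set of 2 (LC2). Arrested spermatocytes from *always early* (*aly*) mutants gave 2. The deposited table gave 12810 genes in RPKM with 1 value per stage, each the authors' mean and so printed with no error. Reads of single libraries were recovered from those means, 20 libraries in all because the LC2 mean holds 3. Libraries are lettered a, b and c here in order of depth. Fitted differences are limma log2 differences of RPKM + 1 from those libraries, given ± SE. Where a side is listed at 0, the fitted difference is no bound on the fold. "Rose" and "fell" are kept for genes that passed the test and reached 8 RPKM on the higher side.

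The niche libraries held 1357959 and 1062226 recovered reads, GB 1606324 and 1446651, S4 2054679 and 1100454, S8 2771803 and 1769077, and S16 808278. EC libraries held 1845469, 1493381 and 1278831, LC1 libraries 4418634, 3784765 and 2522125, LC2 libraries 3034992, 2792142 and 1430233, and *aly* libraries 5098681 and 3769430. A floor of 3 reads in a gene of 1 kb stood at 3.22 RPKM in S16 and, in the shallowest library of each other stage, at 0.879 (*aly*) to 2.78 RPKM (EC). Such floors cover counting error only. The highest gene lay at 0.821 to 1 read per base in each library, and 0 genes lay above 1. This limit of 1 read per base stood at 793 RPKM in niche, 497 in GB, 551 in S4, 352 in S8, 1075 in S16, 772 in EC, 387 in LC1, 546 in LC2 and 248 in *aly*. Ribosomal protein genes lay at a median of 70.6 to 85.6% of it from niche to S16, 54.9% in EC, 40.6% in LC1, 46.6% in LC2 and 48.7% in *aly*, so their differences between stages may follow the limit. The median gene stood at 4.15 RPKM in niche, 4.37 in GB, 5.30 in S4, 5.54 in S8 and 2.41 in S16, against 13.5 in EC, 21.1 in LC1, 15.6 in LC2 and 16.3 in *aly*. Between 6873 and 7806 genes had a read in a niche, GB or spermatogonial library, 10018 to 10878 in an EC library, and 11188 to 12402 in a late or *aly* library. Across genes, which are not replicates, Pearson's r of log2(RPKM + 1) averaged 0.923 over the 14 pairs of libraries within a stage. It averaged 0.882 between the spermatogonial stages, 0.728 between spermatogonia and EC, 0.565 between EC and late spermatocytes, 0.826 between EC and *aly*, and 0.587 between late spermatocytes and *aly*.

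The gene *aly*, a component of the testis-specific meiotic arrest complex (tMAC), is given first because its mutation marks one group. Its RNA had no read in any of the 5 spermatogonial libraries. It stood at 22.3 and 42.2 RPKM in the GB libraries, from 108 and 182 reads, and at 0.619 (2 reads) and 0 in the niche libraries. EC libraries held 138, 109 and 63.0 RPKM, LC1 libraries 57.9, 70.2 and 65.3, and LC2 libraries 61.9, 42.3 and 48.9. The mutant cysts still held 33.4 and 30.4 RPKM. On BDGP6.54, *aly* (FBgn0004372) lies on 3L at 3024129 to 3026521, *bam* (FBgn0000158) on 3R at 25243039 to 25245109, and *can* (FBgn0011569) on 3L at 10263909 to 10267111. *twe* (FBgn0002673) lies on 2L at 16259414 to 16261877, *fzo* (FBgn0011596) on 3R at 23201644 to 23204034, *dj* (FBgn0019828) on 3R at 7059315 to 7060524, and *Mst87F* (FBgn0002862) on 3R at 13827151 to 13828008. All of these are annotated as protein-coding. *kl-3* (FBgn0001314) is on the Y chromosome and has no coordinates in that annotation. The authors' build is not known here.

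**Figure D1:**
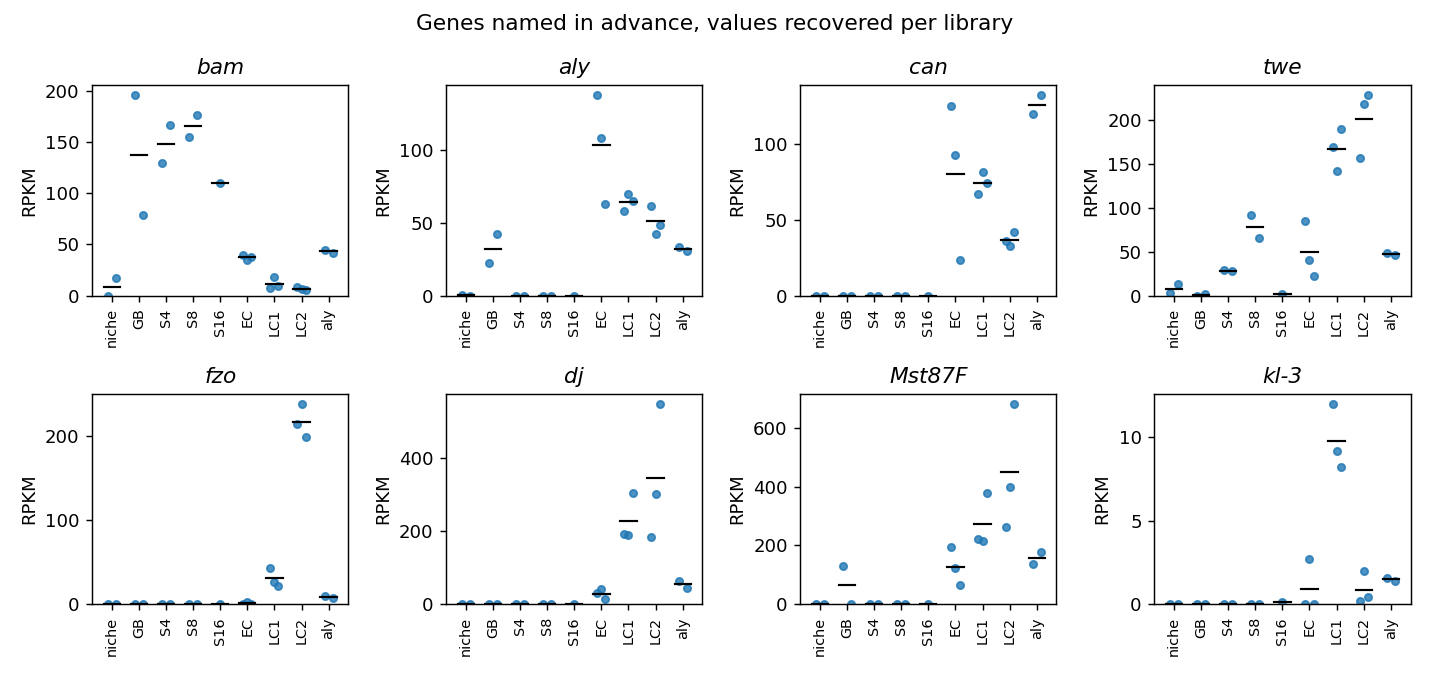
RPKM per recovered library (points) and stage mean (lines) of 8 genes named in advance, by stage, each panel with its own linear axis from 0. *bam* was highest from GB to S16 (110 to 165 RPKM), *can* was at 0 before EC and at 80.5 in EC, and *fzo* was at 217 in LC2 against 30.9 in LC1.

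In GB compared with niche, which asks what differs as a stem cell daughter leaves the niche, genes of the signalling centre were low and the differentiation gene *bam* was high. *gbb*, a BMP ligand of the hub, stood at 199 RPKM in niche and 4.42 in GB. *os* (upd1), the JAK-STAT ligand of the hub, stood at 26.8 and was listed at 0 in GB, and the JAK-STAT target *Socs36E* at 31.1 and 0. *esg*, a transcription factor of hub and stem cells, stood at 28.4 and 0.575, and *tj*, a marker of early somatic cyst cells, at 42.4 and 6.53. *bam*, the switch from amplification to differentiation, stood at 8.40 in niche and 137 in GB, where the libraries held 196 and 78.4. The largest differences also included *lin-28*, an RNA-binding protein, at 189 in niche and listed at 0 in GB, *Her* at 509 and 1.28, *7B2* at 147 and 0, and *gnu* at 97.4 and 0. On the GB side they were the digestive proteases *Jon65Aiv* (198) and *Jon65Aiii* (178), the cuticle gene *Cpr64Ad* (110) and the troponin *TpnC47D* (92.8), all listed at 0 in niche. The libraries of GB and niche did not overlap in any of these 8 largest differences, which were picked for their size. Both other groupings of the same 4 libraries, with genes picked anew, gave 4 of 8. In total, 1111 genes were at least 4-fold higher and 1106 at least 4-fold lower in GB. The median gene moved by 0.17 when scaled to total reads and 0.12 under quantile scaling. Without GB library b the lower count was 1851 and the higher count was 1648 without niche library b.

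Hub markers had a median log2 difference of -2.11 (camera adjusted p = 0.00791, and 0.196 with an estimated correlation). Mitosis genes had a median of -1.13, which was -0.64 under quantile scaling (adjusted p = 0.00791, and 0.64 with an estimated correlation), with *aur* at 49.2 RPKM in GB and 204 in niche and *CycB3* at 0.575 and 28.6. Muscle genes had a median of 1.73 (adjusted p = 0.0124, and 0.64 with an estimated correlation). Ribosomal protein genes had a median of -0.76, beside a difference of -0.67 in the limit of 1 read per base, that became 0.03 under quantile scaling (adjusted p = 1.57e-09, and 0.747 with an estimated correlation). No gene is called in this comparison or in the next 3, because limma made over 5% of false calls in simulated data of these groups.

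In S4 compared with GB, the step into transit amplification, replication and mitosis genes were higher in S4. *DNApol-alpha50*, a primase subunit, stood at 108 RPKM in S4 and 0.336 in GB, the replication licensing genes *Mcm2* at 119 and 33.0 and *dup* at 100 and 29.1, and *CycB3* at 40.0 and 0.575. The replication list had a median log2 difference of 1.23 (camera adjusted p = 0.00597, and 0.555 with an estimated correlation). The mitosis list had a median of 0.88 (adjusted p = 0.000526, and 0.547 with an estimated correlation). The other large values in S4 were those of *PGRP-SC2* (137, from 0 and 274 in libraries a and b, and listed at 0 in GB), the yolk protein gene *Yp3* (140, and 1.06 in GB) and *fsd* (76.6, and 0). Higher in GB were *sug* (98.3, and 0.280 in S4), the protease gene *Jon25Biii* (84.8, and 0), the neuropeptide gene *Lk* (49.6, and 0) and *Mst87F* (64.7, and 0). The GB values of the latter pair came from 1 library each, at 99.1 for *Lk* and 129 for *Mst87F*, with 0 in the other. The dosage compensation RNA *roX2* stood at 14.8 in GB and was listed at 0 in S4. There were 883 genes at least 4-fold higher and 772 at least 4-fold lower in S4. The higher count was 1753 without GB library b and 1214 without GB library a. The libraries did not overlap in 5 of the 8 largest differences, and in 3 and 5 when the same libraries were grouped otherwise.

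In S8 compared with S4, successive mitotic divisions, the values of both Cdc25 phosphatase genes were higher in S8. *stg*, which drives mitotic entry, stood at 74.8 RPKM in S8 and 26.1 in S4, and *twe*, which drives the meiotic divisions, at 78.6 and 28.3. The largest differences toward S4 were *yip7* (230 in S4 and 0.486 in S8), *PGRP-SC2* (137 and 0), the lysozyme *LysE* (80.4 and 0) and *Phae2* (51.8 and 0). All 4 came from S4 library b, at 460, 274, 161 and 104, against 0.392, 0, 0 and 0 in library a. Toward S8 they were *skpB* (64.0 and 0.247), *Obp56a* (46.5 and 0), *Lk* (29.1 and 0) and *sced* (27.2 and 0). The libraries of S8 and S4 did not overlap in 4 of these 8, all of them toward S8, and in 4 and 5 when the same libraries were grouped otherwise. Ribosomal protein genes had a median log2 difference of -0.57, which was -0.10 under quantile scaling (camera adjusted p = 4.17e-19, and 0.866 with an estimated correlation), beside a difference of -0.65 in the limit of 1 read per base. General respiratory chain genes had one of -0.45, which was -0.13 under quantile scaling (adjusted p = 0.00445, and 0.866 with an estimated correlation). At 4-fold, 435 genes were higher and 445 lower. The higher count was 847 without S4 library a and 921 without S4 library b, and the lower count 733 without S8 library b.

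In S16 compared with S8, the end of the mitotic divisions, cell cycle genes were low in S16. *stg* stood at 74.8 RPKM in S8 and was listed at 0 in S16, *RnrS*, a subunit of ribonucleotide reductase, at 254 and 25.5, *CycB* at 77.0 and 4.80, and *CycE* at 40.5 and 0.663. The replication list had a median log2 difference of -2.14 (camera adjusted p = 1.05e-07, and 0.161 with an estimated correlation). The mitosis list had one of -1.53 (adjusted p = 1.25e-09, and 0.0598 with an estimated correlation). Ribosomal protein genes had a median of 1.53, which was 0.15 under quantile scaling (adjusted p = 3.78e-50, and 0.161 with an estimated correlation). They lay at 70.6 and 78.7% of the limit of 1 read per base, which itself differed by 1.61. With a correction for that limit their median was 1.38, but the correction scales with the limit itself. No direction is therefore given for them. Heat shock genes had a median of 1.28, which was 0.46 under quantile scaling (adjusted p = 1.58e-06, and 0.0598 with an estimated correlation), with *Hsp22* at 55.4 and 10.1. Muscle genes had one of -2.59 (adjusted p = 1.25e-09, and 0.0598 with an estimated correlation), with *Tm2*, a tropomyosin, at 0 and 32.2. *Rbp4*, an RNA-binding protein of spermatocytes, stood at 28.4 in S16 and 0.430 in S8. The largest differences toward S16 were *mir-1011* (179 and 0), *GstE3* (95.9 and 0.180), the 7SK small nuclear RNA (*snRNA:7SK*, 75.8 and 0) and *betaNACtes4* (58.4 and 0). Toward S8 they were *stg* and the cuticle genes *Lcp65Af* (160 and 0), *Lcp65Ag3* (81.8 and 0) and *Cpr78Cc* (79.5 and 0, with 0 in S8 library a and 159 in b). S16 has a single library of the lowest depth. There, 296 genes were at least 4-fold higher and 1050 lower, which was 470 and 763 under quantile scaling. Scaling to total reads moved the median gene by -0.18. The higher count was 461 to 468 without 1 of the S8 libraries.

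In EC compared with the 5 spermatogonial libraries, which asks what changes when mitosis ends and the spermatocyte programme starts, the meiotic arrest genes switched on together. Of 14 tested members of tMAC and the testis TAFs, 13 rose and 0 fell (13 rose adjusted over the list alone). The median log2 difference was 5.54 (camera adjusted p = 4.66e-09, and 0.149 with an estimated correlation). *aly* rose by 6.63 ± 0.35 (adjusted p = 8.44e-09), and *wuc*, a tMAC subunit, was listed at 0 in S4, S8 and S16 and stood at 152 RPKM in EC (7.15 ± 0.36, adjusted p = 6.67e-09). *can*, a testis TAF, went from 0 in all 5 libraries to 125, 92.8 and 23.2 in the EC libraries (6.04 ± 0.44, adjusted p = 1.13e-07). *CG13597* (tbrd-1), a bromodomain protein of spermatocytes, went from 0 to 174 (7.41 ± 0.31, adjusted p = 1.57e-09). The largest difference was that of *CG9975* (fest), a gene of meiotic translation, at 0.246, 0 and 2.82 in S4, S8 and S16 and 442 in EC (8.29 ± 0.34, adjusted p = 1.57e-09). *bam* stood at 37.8 in EC and 110 to 165 in spermatogonia and fell by 1.92 ± 0.65 (adjusted p = 0.029). That call was lost without S4 library b (-1.84), S8 library b (-1.88), EC library a (-1.96), b (-1.87) or c (-1.92).

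Genes of the sperm were already on in EC. Of 25 tested spermatid genes 22 rose and 0 fell (22 adjusted over the list alone), with a median of 5.77 (adjusted p = 1.74e-12, and 0.203 with an estimated correlation). *ocn*, a testis protein, was listed at 0 in all spermatogonia and stood at 199 RPKM in EC, *S-Lap1*, a sperm leucyl aminopeptidase, at 131, *loopin-1* at 128 and *dj*, a protein of the sperm tail, at 29.2 (4.47 ± 0.51, adjusted p = 6.37e-06). *Mst87F* rose from 0, 0 and 2.29 in S4, S8 and S16 to 128 (adjusted p = 1.14e-04, SE 1.02), while *fzo* (1.38), *kl-3* (0.901) and *twe* (49.4, a difference of 0.64 ± 0.49) were not called. Of 11 cup and comet genes, described as transcribed after meiosis, 6 rose and 0 fell (6 adjusted over the list alone; adjusted p = 4.16e-05, and 0.203 with an estimated correlation), with *soti* at 38.9 and *c-cup* at 38.1. Testis-specific respiratory chain paralogues rose in 8 of 12 (8 adjusted over the list alone; adjusted p = 0.00213, and 0.281 with an estimated correlation), and 2 fell when scaled to total reads. *CG5389* (ATPsynbetaL) reached 214 (7.25 ± 0.39). Their general partners fell in 4 of 11 (10 when scaled to total reads; 4 adjusted over the list alone; adjusted p = 3.70e-05, and 0.241 with an estimated correlation), including *Cyt-c-p*, from 213 to 293 in S4, S8 and S16 to 71.1 (-2.02 ± 0.38). Testis proteasome paralogues rose in 7 of 13 (8 adjusted over the list alone; adjusted p = 0.00024, and 0.241 with an estimated correlation), with *Rpt6R* at 158 (5.24 ± 0.59) and *Rpn12R*, outside the list, at 126 (6.89 ± 0.36). Their general partners had 0 calls of 9 by limma over all genes, 0 over the list alone and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.132), but when scaled to total reads 4 fell and the median went from -0.05 to -0.61. Further genes listed at 0 in spermatogonia were *Ppm1* (136), *Pk34A* (122), *Ssl* (121) and *Dpy-30L2* (117).

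The amplification programme was low in EC. Replication genes fell in 9 of 14 and rose in 0 (9 adjusted over the list alone), with a median of -1.59, and -2.65 under quantile scaling (adjusted p = 4.66e-09, and 0.203 with an estimated correlation). *RnrS* stood at 227, 254 and 25.5 RPKM in S4, S8 and S16 and 5.14 in EC (-4.65 ± 0.57, adjusted p = 1.30e-05), and *Mcm7* at 171, 161, 19.7 and 14.3 (-2.89 ± 0.35). Mitosis genes fell in 7 of 15 and rose in 2 (0 rose when scaled to total reads; 8 and 2 adjusted over the list alone; adjusted p = 0.000383, and 0.241 with an estimated correlation), with *stg* at 26.1, 74.8 and 0 against 0.709 (-3.85 ± 0.63). Ribosome biogenesis genes fell in 4 of 10 (7 when scaled to total reads; 4 adjusted over the list alone; adjusted p = 0.000292, and 0.241 with an estimated correlation), with *NHP2*, a nucleolar RNA modification protein, going from 294 to 649 down to 81.1 (-2.34 ± 0.31). Muscle genes fell in 6 of 10 (6 adjusted over the list alone; adjusted p = 9.7e-06, and 0.203 with an estimated correlation), with *Mlc2* at 55.3, 80.8 and 14.6 against 1.85 (-3.71 ± 0.67). Ribosomal protein genes fell in 3 of 92 (3 adjusted over the list alone; adjusted p = 0.014, and 0.837 with an estimated correlation). Their median was 0.12 and mean 0.08, the test pointed down, and when scaled to total reads 17 fell and the median was -0.43. With the correction for the limit of 1 read per base 12 of them fell, and 9 of the general respiratory genes. *zpg*, a germline gap junction protein, fell from 196 to 291 to 39.3 (-2.72 ± 0.50, adjusted p = 4.81e-04). *CG14545* (258, 228 and 30.1 against 0.815, -6.55 ± 0.60), the lipid-binding protein *Npc2g* (147, 151 and 18.0 against 0.704, -5.85 ± 0.46) and *Dbi* (53.0 and 12.5 in S8 and S16 against 0) fell furthest among genes whose libraries did not overlap. *GstD7* (240, 144 and 1.5 against 0.863), the trypsins *alphaTry* (S4 215) and *betaTry* (S4 206), and *CG16712* (254, 153 and 0 against 0) also fell, with libraries that overlapped.

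Other lists split. Germline regulators rose in 3 and fell in 3 of 12 (2 and 4 when scaled to total reads or by quantiles; 5 and 3 adjusted over the list alone), with *mei-P26*, a partner of *bam*, at 77.8 RPKM in EC (3.48 ± 0.76). Genes of piRNA silencing rose in 4 and fell in 2 of 20 (1 and 2 over the list alone). When scaled to total reads or by quantiles 1 rose and 5 fell, and their median of 0.40 was -0.15 and 0.12. Both medians were above 0 while the camera test pointed down (adjusted p = 0.683 and 0.278). JAK-STAT and BMP components rose in 5 and fell in 1 of 10 (2 and 1 under quantile scaling; 5 and 1 over the list alone; adjusted p = 0.692), with the kinase *hop* at 60.2. Polycomb and Trithorax genes rose in 5 and fell in 1 of 11 (5 and 1 over the list alone; adjusted p = 0.993), and their median of 0.93 was -0.51 under quantile scaling, where 3 rose and 3 fell, while camera pointed down. Dosage compensation genes rose in 4 of 8 (4 over the list alone; adjusted p = 0.23), with *mle*, the helicase of the complex, at 92.5 (3.06 ± 0.35, adjusted p = 6.86e-06) and *msl-2* at 20.7. Meiosis genes rose in 3 and fell in 1 of 10 (3 and 1 over the list alone; adjusted p = 0.692), with *Rbp4* at 385 and *bol*, a translational regulator of meiosis, at 55.0 (3.67 ± 0.54). Their median of 0.55 was -0.14 under quantile scaling. Y-linked genes rose in 1 of 8 (1 over the list alone; adjusted p = 0.692; median 0.58, and -0.25 under quantile scaling). Axonemal dyneins off the Y rose in 1 of 4 (1 over the list alone; adjusted p = 0.125). Hub markers had 1 rise and 1 fall of 8 (the same over the list alone; adjusted p = 0.993), cyst cell markers 2 rises of 8 (0 under quantile scaling; 1 over the list alone; adjusted p = 0.692), and haemocyte and fat body markers 2 rises and 2 falls of 7 (2 and 2 over the list alone; adjusted p = 0.692). The medians of these 3 lists, 0.44, 0.98 and 0.42, changed sign under quantile scaling, to -0.30, -0.43 and -0.74, and camera pointed down for the hub and haemocyte lists. Heat shock genes had 1 fall of 7 (1 over the list alone; adjusted p = 0.108), with a median of 0.07, a mean of -0.35 and a median of -0.29 under quantile scaling.

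Over all genes, 2341 were at least 4-fold higher and 707 at least 4-fold lower in EC by stage values. Limma called 2748 higher and 878 lower of 12366 tested. The balance depended on the scaling: the median gene moved by -0.41 when scaled to total reads and by -0.71 under quantile scaling. The 4-fold counts were then 1856 and 1067, and 1214 and 1435. The called counts were 2061 and 1760, and 2152 and 1567. Without EC library a the lower calls were 539, and without EC library b 555. All 3 EC libraries lay beyond the spermatogonial mean in 20 of the 20 largest differences, and the sides did not overlap in 13. The 55 other groupings of these libraries gave 0 to 11 of 20. With 1 library left out in turn, general respiratory genes fell in 2 to 8 and mitosis genes in 3 to 7, piRNA genes rose in 1 to 4, and germline regulators fell in 1 to 3. EC library c stood nearer to spermatogonia (r of 0.757 to 0.838) and further from late spermatocytes (0.360 to 0.579) than EC library a (0.623 to 0.718 and 0.515 to 0.711).

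**Figure D2:**
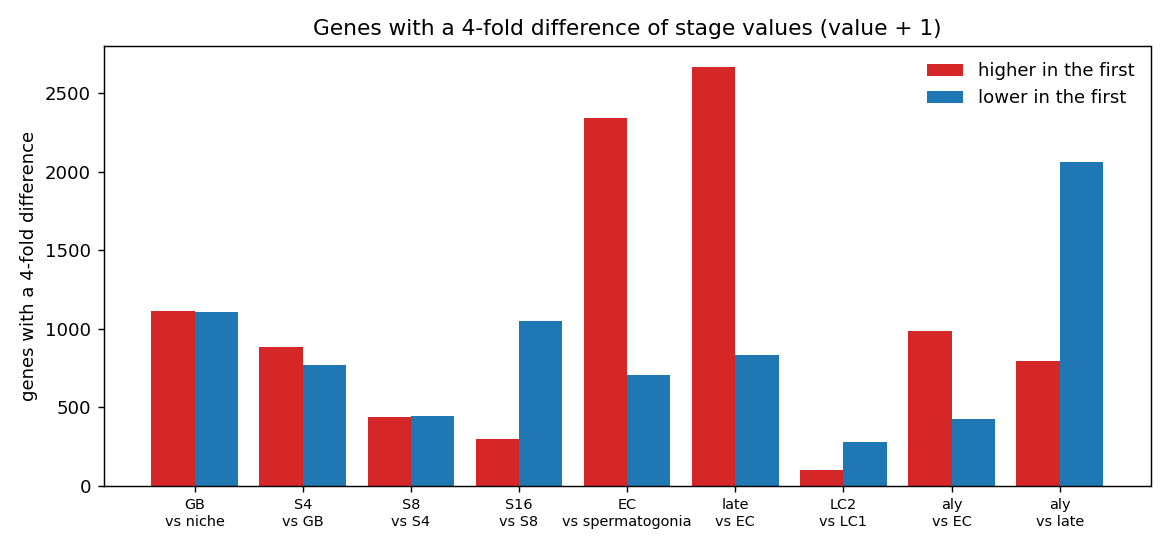
Number of genes (linear axis from 0) with at least a 4-fold difference of stage values + 1 in each of the 9 comparisons, higher (red) or lower (blue) in the stage named first. The largest bars were 2668 genes higher in late spermatocytes than in EC and 2341 higher in EC than in spermatogonia, a count that was 1214 under quantile scaling.

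In late spermatocytes compared with EC, general genes of translation and protein turnover fell while testis-specific paralogues rose. The late side holds 6 libraries, LC1 and LC2 weighted 3 to 2, and the comparison asks how the programme matures during the growth phase. Of 92 ribosomal protein genes 88 fell and 3 rose (88 and 3 adjusted over the list alone), with a median log2 difference of -1.15 (camera adjusted p = 1.3e-15, and 0.354 with an estimated correlation). The median was -1.34 under quantile scaling and -1.25 with the correction for the limit of 1 read per base, a limit that differed by -0.73. *RpLP0-like* went from 172 RPKM in EC to 28.7 in LC1 and 22.4 in LC2 (-2.73 ± 0.39). The 3 that rose included the paralogues *RpL10Aa*, from 7.93 to 243 and 387 (5.22 ± 0.42), and *RpS28-like*, from 6.18 to 98.4 and 217 (4.27 ± 0.37, adjusted p = 1.79e-07). *RpS28a* was listed at 0 in EC and stood at 45.1 and 184. The general proteasome genes fell in 9 of 9 (9 adjusted over the list alone; adjusted p = 0.000229, and 0.226 with an estimated correlation), with *Rpt3* going from 144 to 24.7 and 16.0 (-2.71 ± 0.37). The testis proteasome paralogues rose in 10 of 13 and fell in 1 (10 and 1 adjusted over the list alone; adjusted p = 0.000681, and 0.226 with an estimated correlation), with *Prosbeta5R* going from 5.30 to 244 and 359 (5.94 ± 0.47). The testis respiratory paralogues rose in 7 of 12 and fell in 1 (10 and 1 adjusted over the list alone; adjusted p = 0.0286, and 0.369 with an estimated correlation), with *CG30093* (COX6AL) going from 3.33 to 188 and 428 (6.50 ± 0.55). Their general partners fell in 3 of 11 (5 when scaled to total reads and all 11 under quantile scaling; 3 adjusted over the list alone; adjusted p = 0.0263, and 0.471 with an estimated correlation), with *ATPsyn-beta* going from 375 to 92.8 and 70.2 (-2.11 ± 0.37). Some markers of other cell types rose beside these lists. Cyst cell markers rose in 3 of 8 (3 over the list alone; median 1.1, adjusted p = 0.581; under quantile scaling 2 rises, 1 fall and a median of 0.39), hub markers in 2 of 8 (2 over the list alone; median 0.89, and 0.30 under quantile scaling, adjusted p = 0.161) and muscle markers in 2 of 10 (2 over the list alone; median 1.03, adjusted p = 0.289; under quantile scaling 1 and a median of 0.32), with 0 falls in each as deposited. Haemocyte and fat body markers had 0 calls of 7 (adjusted p = 0.581).

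Genes of spermatid construction rose. All 11 cup and comet genes tested rose (11 adjusted over the list alone), with a median of 3.96 (adjusted p = 1.34e-05, and 0.226 with an estimated correlation). *t-cup* went from 2.08 RPKM in EC to 186 and 360 (6.70 ± 0.47, adjusted p = 3.09e-08) and *schuy* from 5.48 to 180 and 188 (4.98 ± 0.39). Spermatid genes rose in 22 of 25 (22 adjusted over the list alone; adjusted p = 0.000185, and 0.354 with an estimated correlation). *Mst35Bb*, a protamine, went from 18.0 to 166 and 307 (3.48 ± 0.41), *dj* from 29.2 to 227 and 344 (3.20 ± 0.50, adjusted p = 6.61e-05) and *fzo*, the mitofusin of spermatids, from 1.38 to 30.9 and 217 (4.90 ± 0.34, adjusted p = 2.58e-08). *Mst87F* stood at 272 and 448 and was not called (1.42 ± 0.99, adjusted p = 0.255). Y-linked genes rose in 6 of 8 and fell in 1 (6 and 1 adjusted over the list alone; adjusted p = 0.0124, and 0.283 with an estimated correlation), with *Pp1-Y2*, a phosphatase, going from 0.167 to 43.7 and 51.4 (5.34 ± 0.30). *kl-3*, a Y-linked axonemal dynein, stood at 9.79 in LC1 and 0.867 in LC2 and its late mean did not reach the 8 RPKM needed for a call (1.73 ± 0.39). Axonemal dyneins off the Y rose in 3 of 4 (3 adjusted over the list alone; adjusted p = 0.0302, and 0.283 with an estimated correlation), with *Dhc16F* going from 0.610 to 61.2 and 16.5 (4.58 ± 0.31). The mitochondrial carriers *Dic4* (0.629 to 108 and 148, 6.30 ± 0.33) and *Ucp4C* (2.07 to 178 and 251, 6.16 ± 0.36), the chaperonin *Hsp60D* (1.21 to 191 and 192, 6.59 ± 0.43) and *CG11165* (azot; 1.15 to 194 and 339, 6.96 ± 0.45) were among the largest rises. *CG42693* (72.4 and 183) and *Peritrophin-15b* (48.1 and 95.7) were listed at 0 in EC, as were the small nucleolar RNAs *snoRNA:Me18S-C1096* (39.0 and 169) and *snoRNA:185* (6.98 and 179), which can share reads with host genes.

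Early germline genes fell. Of 12 germline regulators 7 fell and 1 rose (7 and 1 adjusted over the list alone; adjusted p = 0.0543). Of 20 piRNA genes 13 fell and 2 rose (13 and 2 adjusted over the list alone; adjusted p = 0.00142, and 0.226 with an estimated correlation). *aub*, a Piwi-family protein, went from 267 RPKM to 28.4 and 9.28 (-4.08 ± 0.45) and *shu* from 73.7 to 1.97 in LC2 (-4.12 ± 0.57). *vas*, the germline helicase, went from 129 to 14.4 and 4.62 (-4.00 ± 0.57), in a row whose identifier is now shared with *solo*. *Unr*, a translational regulator, went to 9.59 and 3.14 (-4.42 ± 0.58), and *Sse*, separase, from 35.2 to 3.27 and 0.235 (-4.16 ± 0.59). *mld*, *Bgb*, *CG12590* and *CG1737* also fell, from -3.65 to -4.12. Ribosome biogenesis genes fell in 8 of 10 (9 adjusted over the list alone; adjusted p = 0.000185, and 0.226 with an estimated correlation), with *mod*, a nucleolar protein, going from 237 to 33.4 and 6.09 (-4.12 ± 0.57). Polycomb and Trithorax genes fell in 5 of 11 (5 adjusted over the list alone; adjusted p = 0.0112, and 0.226 with an estimated correlation), with *brm* falling from 59.1 to 8.96 and 2.42 (-3.27 ± 0.35). JAK-STAT and BMP components fell in 3 of 10 (7 under quantile scaling; 3 adjusted over the list alone; adjusted p = 0.0329, and 0.226 with an estimated correlation). *bam* fell from 37.8 to 11.8 and 6.78 (-1.94 ± 0.63, adjusted p = 0.018), a call lost without EC library a (-1.90) or c (-1.93). The meiotic arrest list had 0 rises and 2 falls of 14 (camera adjusted p = 0.247, 0 of either over the list alone, and 0 and 3 at an unadjusted limma p under 0.05), with 5 falls under quantile scaling, where its median went from -0.37 to -0.94. *aly* (-0.74 ± 0.34) and *can* (-0.21 ± 0.43) were not called. For the divisions to come, *twe* rose from 49.4 to 167 and 201 (2.04 ± 0.48, adjusted p = 0.002), *CycB* from 8.43 to 155 and 185 (4.17 ± 0.72, adjusted p = 1.67e-04) and the kinase *aur* from 43.7 to 175 and 207 (2.12 ± 0.31). The mitosis list as a whole had 4 rises and 2 falls of 15 (4 and 2 over the list alone; median 0.36, and -0.16 under quantile scaling; adjusted p = 0.766).

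Over all genes, 2668 were at least 4-fold higher and 834 at least 4-fold lower in late spermatocytes. With LC1 alone these were 2544 and 635, and with LC2 alone 2745 and 1560. Limma called 2853 higher and 2492 lower. The median gene moved by -0.57 under quantile scaling, where the 4-fold counts were 2231 and 2082 and the called counts 2650 and 3993. Late and EC libraries did not overlap in 19 of the 20 largest differences, *snoRNA:185* being the exception, and 83 other groupings of these libraries gave 0 to 16. With 1 library left out in turn, germline regulators fell in 2 to 6, piRNA genes in 8 to 12 and meiotic arrest genes in 0 to 4, and spermatid genes rose in 14 to 21. *snoRNA:Me18S-A1576* was the only one of the 20 to lose its call, without EC library c (-2.83).

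In LC2 compared with LC1, both labelled late spermatocyte, with no difference given in the labels, dynein RNAs fell and *fzo* rose. Falls were not confined to dyneins, and whether they follow transcript length was not tested. All 4 tested axonemal dyneins off the Y fell (4 adjusted over the list alone), with a median log2 difference of -2.23 (camera adjusted p = 2.62e-05, and 0.177 with an estimated correlation). *Dhc98D* went from 85.8 RPKM in LC1 to 15.3 in LC2 (-2.43 ± 0.38, adjusted p = 0.002) and *Dhc16F* from 61.2 to 16.5 (-1.83 ± 0.36, adjusted p = 0.008). *Dhc36C*, from 105 to 22.6, lost its call without LC1 library c (-2.15) or LC2 library c (-1.96). *Dhc62B* lost it without LC1 library a (-2.11) or c (-2.21) or LC2 library b (-2.33) or c (-2.02). Y-linked genes fell in 4 of 8 (4 adjusted over the list alone; adjusted p = 0.0197, and 0.478 with an estimated correlation). *kl-3* went from 12, 9.18 and 8.20 in the LC1 libraries to 0.206, 1.98 and 0.412 in the LC2 libraries (-2.64 ± 0.45, adjusted p = 0.004). *kl-5*, from 24.0 to 4.59, lost its call without LC1 library a (-2.05) or LC2 library c (-1.87), and *kl-2*, from 15.8 to 3.05, without LC1 library a (-2.01) or LC2 library c (-1.77). *Ory* lost it without any 1 of the LC1 libraries or LC2 library a or c. *fzo* rose from 43.6, 26.9 and 22.1 in the LC1 libraries to 214, 238 and 198 in the LC2 libraries (2.83 ± 0.39, adjusted p = 9.11e-04).

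The 4 largest falls in LC2 follow. *Pkd2*, a channel of the sperm tail, fell from 165 RPKM to 6.31 (-4.74 ± 0.72, adjusted p = 0.002), *osm-6* (IFT52), of intraflagellar transport, from 45.6 to 1.37 (-4.45 ± 0.41), *Osbp*, an oxysterol-binding protein, from 67.9 to 1.72 (-4.65 ± 0.46) and *snmRNA:765* from 78.6 to 2.47 (-5.23 ± 0.90). *shg*, the E-cadherin gene and a hub marker, fell from 30.8 to 3.24 (-3.14 ± 0.57). Haemocyte and fat body markers rose in 2 of 7 (2 over the list alone; median -0.50, and -0.10 under quantile scaling, mean 0.22, adjusted p = 0.583), among them *Fbp1*, from 2.64 to 28.2 (3.12 ± 0.55). Cyst cell markers fell in 1 of 8 (1 over the list alone; median -0.83, adjusted p = 0.0538; under quantile scaling 0 and a median of -0.54). Of the largest rises, *Lsp1alpha*, a larval storage protein, went from 0.0405 to 27.8 (4.48 ± 0.45, adjusted p = 8.05e-05) and *snoRNA:185* from 6.98 to 179. *Obp99b* (13.0 to 352) lost its call without LC1 library c (4.40) or LC2 library c (4.88), and *TwdlD* (0.205 to 58.7) without LC1 library c (5.45). Ribosomal protein genes had a median of 0.72, which was 0.44 under quantile scaling, beside a difference of 0.50 in the limit of 1 read per base (adjusted p = 5.82e-23, and 0.478 with an estimated correlation), with 3 of 92 rising over all genes and 34 over the list alone. The 3, *RpS14a*, *RpS14b* and *RpS19a*, each lost the call without any 1 of the LC1 libraries or LC2 library b or c, while 35 rose when scaled to total reads, 16 with the correction for that limit, and 23 rose and 1 fell under quantile scaling. General respiratory genes rose in 1 of 11, *CoIV*, which lost its call without the same libraries (7 rose under either other scaling, and 7 over the list alone; adjusted p = 5.29e-05, and 0.424 with an estimated correlation). Spermatid genes rose in 1 of 25 (1 over the list alone), with a median of 0.47 that was -0.11 under quantile scaling (adjusted p = 0.00814, and 0.575 with an estimated correlation). *can* stood at 74.4 and 37.0 (-0.99 ± 0.49), *aly* at 64.4 and 51.0 (-0.35 ± 0.39), *twe* at 167 and 201, *dj* at 227 and 344, *bam* at 11.8 and 6.78 and *Mst87F* at 272 and 448, none of them called.

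In total 98 genes were at least 4-fold higher and 280 lower in LC2, and 205 and 260 under quantile scaling. The median gene moved by 0.15 when scaled to total reads and 0.12 under quantile scaling. Without LC2 library a these were 155 and 449. Limma called 140 higher and 420 lower, and these counts moved with every library and scaling. They were 58 and 185 without LC1 library a, 43 and 202 without b and 29 and 151 without c. They were 408 and 568 without LC2 library a, 37 and 191 without b and 42 and 147 without c. Quantile scaling gave 557 and 654, and total reads gave 408 and 274, so the side with more calls changed. All 8 largest differences had libraries that did not overlap, and the 9 other groupings gave 0 to 4 of 8. With 1 library left out in turn, dyneins off the Y fell in 2 to 4 and Y-linked genes in 1 to 4, and ribosomal protein genes rose in 0 to 29, general respiratory genes in 0 to 6, and haemocyte and fat body markers in 1 or 2.

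In arrested *aly* cysts compared with EC, which asks how far the mutant cysts stand from the stage they resemble, the meiotic arrest genes were still on. Of 14 tested members 0 rose and 1 fell (1 adjusted over the list alone). The median log2 difference was -0.04 (mean 0.05, and a median of 0.07 when scaled to total reads; camera adjusted p = 0.846). *can* stood at 126 RPKM in *aly* and 80.5 in EC (0.95 ± 0.55, adjusted p = 0.265). The 1 that fell was *aly* itself, from 103 to 31.9 (-1.59 ± 0.44, adjusted p = 0.017), a call lost without *aly* library a (-1.66) or b (-1.53). Spermatid genes rose in 2 of 25 and fell in 0 (9 and 0 under quantile scaling, where the median went from 0.94 to 1.61; 1 and 0 over the list alone; adjusted p = 0.0595), with *fzo* rising from 1.38 to 8.90 (2.13 ± 0.44, adjusted p = 0.003; 0.93 and not called under quantile scaling). Of 11 cup and comet genes 6 rose and 0 fell (6 adjusted over the list alone; adjusted p = 0.00781, and 0.416 with an estimated correlation). *schuy* went from 5.48 to 116 (4.34 ± 0.50, adjusted p = 2.00e-05), *hale* from 14.6 to 136 (3.40 ± 0.52) and *wa-cup* from 6.63 to 50.2 (2.95 ± 0.49). *bam* (43.1 and 37.8), *twe* (47.0 and 49.4), *dj* (54.6 and 29.2), *Mst87F* (157 and 128) and *kl-3* (1.5 and 0.901) were not called.

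Most ribosomal protein genes and part of the general proteasome and respiratory genes fell in *aly* relative to EC, by an amount that depended on the scaling. Ribosomal protein genes fell in 87 of 92 and rose in 1 (88 and 1 adjusted over the list alone), with a median of -1.73 (adjusted p = 1.58e-39, and 0.416 with an estimated correlation). Under quantile scaling 71 fell and the median was -1.07. The limit of 1 read per base differed by -1.64, and they lay at a median of 54.9% of it in EC and 48.7% in *aly*. The limit alone may therefore give these falls. With the correction for that limit 84 fell and the median was -1.78, but the correction scales with the limit itself and does not settle this. *RpL34a* went from 288 RPKM to 46.9 (-2.55 ± 0.36, adjusted p = 1.62e-04). General proteasome genes fell in 6 of 9, with a median of -1.25, and under quantile scaling in 4, with a median of -0.52 (7 adjusted over the list alone; adjusted p = 8.71e-06, and 0.416 with an estimated correlation), with *Pros28.1* (Prosalpha4) going from 292 to 59.0 (-2.28 ± 0.41). General respiratory genes fell in 3 of 11 (7 adjusted over the list alone; adjusted p = 0.000652, and 0.416 with an estimated correlation), with *ATPsyn-beta* going from 375 to 45.1 (-2.88 ± 0.48). Ribosome biogenesis genes fell in 3 of 10 (6 under quantile scaling; 4 adjusted over the list alone; adjusted p = 0.00139, and 0.416 with an estimated correlation), with *Nop56* going from 193 to 29.0 (-2.57 ± 0.46). Genes of piRNA silencing fell in 4 of 20 (8 fell and 2 rose under quantile scaling; 4 adjusted over the list alone; adjusted p = 0.0243, and 0.416 with an estimated correlation), with *aub* going from 267 to 13.1 (-4.23 ± 0.58, adjusted p = 1.20e-04). *vas* also fell (-3.94 ± 0.73), as did *Eap* (77.0 to 4.80, -3.69 ± 0.65) and *CG3358* (59.3 to 2.32, -4.35 ± 0.56). The eye pigment transporter gene *w* fell from 41.3 to 0.0623 (-5.24 ± 0.93, adjusted p = 9.68e-04). The *aly* mutation cannot be told apart here from any other genetic difference of those cysts. *Obp99b* lost its call without *aly* library a (-4.14), *lig3* without *aly* library a (-3.96) or b (-4.32), and *CG15398* without a (-3.66) or b (-4.15).

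The largest rises in *aly* cysts were of genes at or near 0 in EC. *en* (70.2 RPKM), a patterning transcription factor, *wg* (37.7), the Wnt ligand, the cuticle gene *Cpr76Bc* (43.6) and *CG4269* (78.1) were listed at 0 in all EC libraries and rose, with adjusted p of 2.24e-08 for *en*. *trpl*, a photoreceptor channel, rose from 0.819 to 71.8 (5.49 ± 0.48, adjusted p = 1.54e-06), *yl*, the yolk protein receptor, from 0.0324 to 40.0 (5.31 ± 0.76), *bgm* from 0.329 to 53.3 (5.42 ± 0.62), the neuropeptide *CCHa1* from 0.947 to 68.6 (5.36 ± 0.54), *pot* from 0.452 to 49.6 (5.09 ± 0.32) and *CR33319* from 0.347 to 138 (6.77 ± 0.60). The haemocyte genes *Pxn* (0.501 to 36.5, 4.71 ± 0.54) and *Hml* (1.15 to 26.9, 3.90 ± 0.53) rose, in a marker list with 2 rises and 2 falls of 7 (2 and 2 over the list alone; adjusted p = 0.716). Muscle markers rose in 1 of 10 (1 over the list alone; median 1.16, and 0.56 under quantile scaling, adjusted p = 0.0899), and hub and cyst cell markers had 0 calls of 8 each. The axonemal dynein *Dhc36C* rose from 2.46 to 52.8 (4.09 ± 0.49) and *aur* from 43.7 to 163 (1.93 ± 0.40). Both *aly* libraries lay beyond all 3 EC libraries in 20 of the 20 largest differences, and the 9 other groupings of these libraries gave 6 to 17. There were 988 genes at least 4-fold higher and 427 lower in *aly*, and 951 and 861 under quantile scaling, where the median gene moved by -0.32. Limma called 1039 higher and 880 lower, and 1410 and 1491 under quantile scaling. Without *aly* library a the calls were 536 and 302, and without *aly* library b 625 and 426. With 1 library left out in turn, ribosomal protein genes fell in 46 to 86, general proteasome genes in 3 to 6, ribosome biogenesis genes in 3 to 5, piRNA genes in 2 to 5, and haemocyte and fat body markers in 0 to 2, while cup and comet genes rose in 3 to 6 and spermatid genes in 1 to 5.

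In *aly* cysts compared with late spermatocytes, which asks what part of the late programme the mutant cysts lack, the late testis-specific genes were low. Testis proteasome paralogues fell in 9 of 13 and rose in 0 (9 adjusted over the list alone), with a median log2 difference of -3.92 (camera adjusted p = 0.000891, and 0.447 with an estimated correlation). *Prosbeta5R* stood at 244 RPKM in LC1, 359 in LC2 and 6.26 in *aly* (-5.33 ± 0.55). Cup and comet genes fell in 6 of 11 (6 adjusted over the list alone; adjusted p = 0.00364, and 0.447 with an estimated correlation), with *t-cup* at 186, 360 and 2.91 (-5.93 ± 0.55) and *d-cup* at 96.0, 119 and 3.51 (-4.48 ± 0.47). Testis respiratory paralogues fell in 7 of 12 (9 adjusted over the list alone; adjusted p = 0.00364, and 0.447 with an estimated correlation), with *CG30093* at 188, 428 and 3.62 (-5.77 ± 0.64). Y-linked genes fell in 5 of 8 (5 adjusted over the list alone; adjusted p = 0.0196, and 0.451 with an estimated correlation), with *Pp1-Y2* at 43.7, 51.4 and 0.367 (-5.09 ± 0.34). Spermatid genes fell in 6 of 25 (5 adjusted over the list alone; adjusted p = 0.0142, and 0.809 with an estimated correlation), with *Mst35Bb* at 166, 307 and 21.6 (-3.17 ± 0.47) and *fzo* at 30.9, 217 and 8.90 (-2.78 ± 0.39, adjusted p = 3.69e-05). *dj* fell (-2.22 ± 0.57, adjusted p = 0.006; lost without *aly* library b, -1.96), and so did *twe* (-1.90 ± 0.55, adjusted p = 0.013; lost without *aly* library a, -1.94, or b, -1.86) and *CycB*, from 155 and 185 to 19.8 (-3.05 ± 0.82, adjusted p = 0.008; lost without *aly* library b, -2.62). *Mst87F* (-1.01 ± 1.14) and *kl-3* (-1.04 ± 0.45) were not called.

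The mitochondrial genes *Dic3* (155 and 234 RPKM in LC1 and LC2, 0.101 in *aly*, -7.37 ± 0.35, adjusted p = 4.79e-09), *Tim17a1* (164 and 308, 1.04, -6.68 ± 0.52) and *Ucp4C* (178 and 251, 1.14, -6.58 ± 0.42) were among the largest falls. *robl37BC*, a dynein light chain gene (160 and 220), *CG34274* (149 and 283) and *CG42493* (129 and 272) were listed at 0 in both *aly* libraries. *laf* (129 and 130, 0.165), *Acyp*, an acylphosphatase (158 and 303, 0.988), *I-3* (137 and 268, 0.752) and *RabX2* (75.4 and 142, 0.139) also fell, from -6.41 to -6.80. The dynein *Dhc16F* fell from 61.2 and 16.5 to 0.727 (-4.43 ± 0.36) and the actin *Act87E* from 197 and 178 to 3.08 (-5.52 ± 0.70). The meiotic arrest list had 0 rises and 0 falls of 14 by limma, over all genes and over the list alone, and 3 and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.495), with 2 rises when scaled to total reads and 6 under quantile scaling. *aly* (-0.85 ± 0.40, adjusted p = 0.106) and *can* (1.15 ± 0.50, adjusted p = 0.081) were not called. *bam* rose to 43.1 from 11.8 and 6.78 (2.13 ± 0.73, adjusted p = 0.032), a call lost without LC1 library a (1.99) or c (2.07) or *aly* library a (2.07) or b (2.19).

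On the higher side, Polycomb and Trithorax genes rose in 5 of 11 (5 adjusted over the list alone; adjusted p = 0.031, and 0.447 with an estimated correlation), with *esc* at 93.5 RPKM in *aly* and 10.1 and 7.52 in LC1 and LC2 (3.26 ± 0.49) and *Sce* at 99.2 against 26 and 24.7 (1.95 ± 0.31, adjusted p = 1.17e-04). Among the 5, *Pc* and *Su(z)12* lost their calls without *aly* library a (3.03 and 1.87) or b (2.89 and 1.82), and the list rose in 2 to 5 with 1 library left out in turn. The piRNA gene *armi* stood at 116 against 41.8 and 13.5 (2.13 ± 0.44), in a list with 5 rises and 2 falls of 20 (8 and 2 under quantile scaling; 5 and 2 over the list alone). The largest rises were *CR33319* (138), *en* (70.2, 4.92 ± 0.30), *trpl* (71.8, 4.91 ± 0.43), *pot* (49.6, 4.87 ± 0.29), *wg* (37.7, 4.45 ± 0.65), *Jhedup* (50.8, 4.94 ± 0.48), the adhesion gene *Cad88C* (55.7, 4.48 ± 0.44), the photoreceptor gene *chp* (33.5, 4.34 ± 0.35) and the clock gene *per* (29.8, 4.34 ± 0.35). Ribosomal protein genes fell in 10 of 92 and rose in 1 (3 and 0 over the list alone), with a median of -0.56 that flipped to 0.25 under quantile scaling, where 27 rose and 5 fell (adjusted p = 0.00332, and 0.857 with an estimated correlation). General respiratory and proteasome genes had 0 calls by limma and 0 at an unadjusted p under 0.05 (median respiratory difference -0.33, and 0.34 under quantile scaling, where 3 rose; median proteasome difference 0.02, and 0.97 under quantile scaling, where 5 of 9 rose). There were 797 genes at least 4-fold higher and 2059 lower in *aly*. The median gene moved by 0.20 when scaled to total reads and 0.30 under quantile scaling, where the 4-fold counts were 1568 and 1911. Limma called 1652 higher and 2166 lower, and 3502 and 2180 under quantile scaling. Without *aly* library a the higher calls were 822, and without *aly* library b 788. All 20 largest differences had libraries that did not overlap, and 27 other groupings gave 0 to 16. With 1 library left out in turn, piRNA genes rose in 2 to 5 and fell in 0 to 2, ribosomal protein genes fell in 2 to 19, spermatid genes in 3 to 7 and general respiratory genes in 0 to 2. Muscle markers had 2 rises and 1 fall of 10, cyst cell markers 1 rise and hub markers 1 fall of 8, and haemocyte and fat body markers 2 rises and 2 falls of 7, the same over each list alone (adjusted p from 0.56 to 0.982).

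Expression from the X chromosome relative to the autosomes changed at both spermatocyte steps. The ratio of the median X-linked gene to the median autosomal gene was 0.976 ± 0.101 in EC (SD, n = 3) and 0.774 ± 0.0505 in spermatogonia (SD, n = 5), a difference of 0.201 (exact two-sided permutation test, p = 0.0179, adjusted p = 0.0179 over the pair of tests). It was 0.599 ± 0.0588 in late spermatocytes (SD, n = 6), a difference of -0.376 from EC (exact two-sided permutation test, p = 0.0119, the smallest of 84 splits, adjusted p = 0.0179). All 3 EC libraries lay above all 5 spermatogonial libraries and all 6 late libraries. The level of the ratio depended on the filter. Without a filter on low values it was 1.234 in EC and 1.018 in spermatogonia, a difference of 0.216 that did not pass (exact permutation p = 0.0893). With genes at a mean of at least 5 it was 0.817 and 0.663 (exact permutation p = 0.0357). A ratio does not show whether the X-linked or the autosomal median moved. By stage the ratio was 0.734 in niche, 0.579 in GB, 0.750 in S4, 0.802 in S8, 0.768 in S16, 0.649 in LC1 and 0.550 in LC2. It was 1.02 in *aly*, where the libraries held 0.975 and 1.06. The mutant ratio was not tested.

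**Figure D3:**
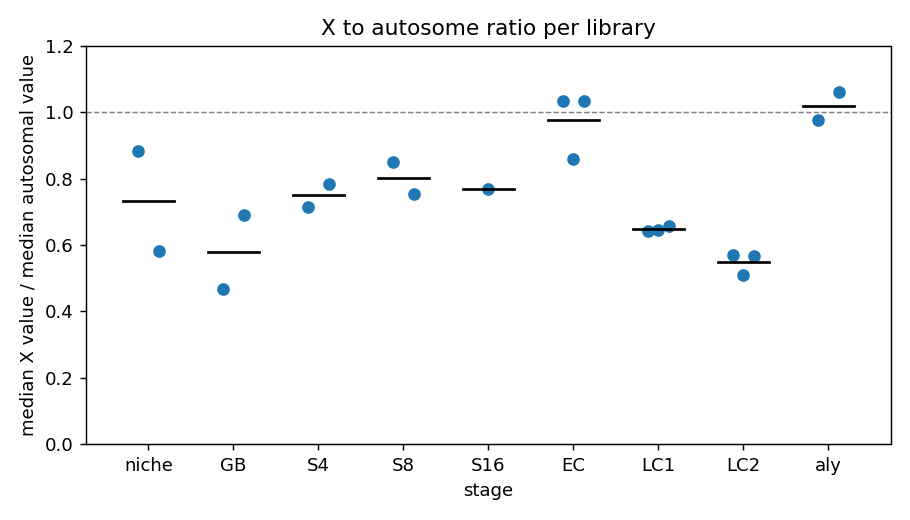
Ratio of the median RPKM of X-linked genes to that of genes on the autosomal arms, per recovered library (points) with the stage mean (line), by stage, and a dashed line at 1. EC libraries lay between 0.859 and 1.035, *aly* libraries at 0.975 and 1.06, and LC1 and LC2 means at 0.649 and 0.550.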

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

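The limma counts and the settings listed above as added were chosen only after the result was seen. No paired analysis was possible because recovered libraries carry no replicate number, so the planned replicate block was not run. A count kept its size when it stayed within 1.5 times, and those that moved are given as genes higher and lower, the cause not tested. With a pseudocount of 0.1 the 4-fold counts were 1420 higher in S4 against GB, 827 and 808 in S8 against S4, 603 and 1647 in S16 against S8, 3702 higher in EC, 237 and 642 in LC2 against LC1, and 1722 and 778 in *aly* against EC. With 5 they were 509 and 547 in GB against niche, 341 and 316 in S4, 77 and 142 in S8, 106 and 371 in S16, 1130 and 287 in EC, 429 lower in late against EC, 26 and 98 in LC2 against LC1, 372 and 160 in *aly* against EC and 274 higher in *aly* against late. Low values decide such counts by construction, since the pseudocount sets how small a value can reach a 4-fold difference. Under quantile scaling they were 470 higher in S16, 1214 and 1435 in EC, 2082 lower in late, 205 higher in LC2 against LC1, 861 lower in *aly* against EC and 1568 higher in *aly* against late. Total reads gave 1067 lower in EC, and LC2 alone 1560 lower in late against EC.

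The limma calls moved as follows. In LC2 against LC1 they were 53 and 178 with a pseudocount of 0.1, 260 and 645 with 5, 557 and 654 under quantile scaling, 408 and 274 under total reads, 223 higher with the correction for 1 read per base, 39 higher by voom, 546 and 1089 with weights, and 736 lower with the 2 sides alone. Quantile scaling gave 1567 lower in EC, 3993 lower in late, 1491 lower in *aly* against EC and 3502 higher in *aly* against late. Total reads gave 1760 lower in EC. Weights gave 1854 and 1613 in *aly* against EC and 3192 higher in *aly* against late, and the 2 sides alone gave 1655 lower and 2836 higher. Leaving out 1 library in turn, the 4-fold counts ranged from 996 to 1851 lower in GB against niche, 784 to 1753 higher in S4 against GB, 379 to 921 higher and 397 to 733 lower in S8 against S4, 461 to 468 higher in S16 against S8 (its lone S16 library cannot be left out), and 82 to 155 higher and 235 to 449 lower in LC2 against LC1. The calls ranged from 539 to 963 lower in EC, 29 to 408 higher and 147 to 568 lower in LC2 against LC1, 536 to 1194 higher and 302 to 860 lower in *aly* against EC, and 788 to 1690 higher in *aly* against late. With the correlation estimated, 0 lists passed camera in any of the 9 comparisons. Without a filter the X ratio of EC differed from spermatogonia by 0.216 and no longer passed.

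Among the values of named genes under the alternatives, 9822 kept direction and side of the threshold, 443 fell short of it, 217 came to pass it and 479 untested differences moved. There were 2 that reversed, both under quantile scaling: *eya* in EC against spermatogonia (-0.34) and *Hsp26* in *aly* against EC (0.09). Depth limits S16 most, whose floor of 3.22 RPKM lies above the median gene of that stage.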

Other observations

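The tests of the limit of 1 read per base and of other groupings of the libraries were chosen only after the result was seen. Those of depth, random loss and muscle RNA were fixed before their outcome was seen.

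Some genes of adult gut, cuticle and blood had high values in part of the germline series, often in 1 of 2 libraries of a stage, and are given as values, chosen after they were seen. The digestive protease *Jon65Aiv* stood at 198 RPKM in GB, 253 in S4 (9.96 and 496 in libraries a and b), 20.6 in S8, 0 in S16 and 0.338 in EC. The trypsin *alphaTry* stood at 25.8, 215 (52.3 and 378 in libraries a and b), 31.4, 0 and 0 in the same stages. The lysozyme *LysE* stood at 80.4 in S4, from 0 and 161 in libraries a and b, at 2.27 in GB, and at 0 in niche, S8, S16 and EC. The larval cuticle gene *Lcp65Af* stood at 44.2 in GB, 140 in S4 (280 and 0 in libraries a and b) and 160 in S8 (11.9 and 308), and at 0 in niche and S16. In *aly* cysts the haemocyte genes *Pxn* and *Hml* stood at 36.5 and 26.9, against 0.501 and 1.15 in EC, while *He*, of the same marker list, stood at 0.454. *w* stood between 20.1 and 41.3 in the 8 other stages and at 0.0623 in *aly*, where the mutation and genetic background cannot be told apart. *Yp3* stood at 54.1 in niche, 140 in S4 and 1.06 in GB. No source of these RNAs was tested.

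The number of genes with a read was higher in EC than in the spermatogonial libraries. With every library thinned to 808278 reads, the 3 EC libraries held 9720 to 10136 genes and the 5 spermatogonial libraries 7242 to 7621, so the lowest EC library held 1.28 times as many as the highest spermatogonial library, which argues against depth. If earlier libraries had lost transcripts at random, genes at 8 to 16 RPKM in S8 would be missed as often as genes at that level in EC. Of 968 such EC genes, 215 (22.2%) had no read in any niche, GB, S4 or S16 library, against 19 of 925 (2.05%) for S8, a ratio of 10.8, which argues against random loss as the whole cause. The start of spermatocyte transcription stays open as a hypothesis, and lower RNA capture that affects some genes more than others was not tested.

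No gene exceeded 1 read per base of its length, and the highest stood at 0.821 to 1 in each of the 20 libraries, although depth differed between libraries. Counting reads that start at the same position as 1 is a candidate explanation, and it would press the values of the most abundant RNAs together. A biological explanation was not tested. With a correction for that limit, the higher calls in LC2 against LC1 were 223 in place of 140. The median log2 difference of ribosomal protein genes stood near that of the limit in GB against niche (-0.76 and -0.67), S4 against GB (0.04 and 0.15), S8 against S4 (-0.57 and -0.65), S16 against S8 (1.53 and 1.61) and *aly* against EC (-1.73 and -1.64). It stood further off in EC against spermatogonia (0.12 and 0.42), late against EC (-1.15 and -0.73), LC2 against LC1 (0.72 and 0.50) and *aly* against late (-0.56 and -0.91). The limit alone may give the near ones. In order, the correction left those at -0.92, 0.03, -0.55, 1.38 and -1.78. At like shares of the limit it returns the limit's own difference, so no test separated the limit from a change in RNA.

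Some muscle genes were high in GB, S4 and S8 and low in niche and S16. *Mlc1* stood at 4.79, 36.4 and 27.9 RPKM in GB, S4 and S8, and *Tm2* at 22.8, 32.7 and 32.2, each at 0 in niche and S16. RNA from the torn muscle sheath is a hypothesis for this, although each cyst was picked singly by needle. It was tested on a wider list of 29 muscle genes, of which 6 (20.7%) reached 8 RPKM in S4 or S8 at no less than 2 times niche and S16. They were *TpnC47D* (59.6 in S4, from 119 and 0 in libraries a and b), *Mp20* (55.0), *Mlp60A* (22.7), *Mlp84B* (18.2 in S8), *Mf* (8.50 in S8) and *Zasp66* (13.8 in S8). A share of 60% had been set for muscle as the source and 20% against it, so the test left this undecided. Of the wider list, *Act88F* (1.88 in S4), *Prm* (0.349), *sls* (0.0257) and *bt* (0.0410) were low. Other members ran against the pattern: *flr* (85.5), *Zasp52* (31.2), *Tm1* (28.2), *kon* (26.5) and *Act79B* (14.7) were higher in niche than in S4 or S8, and *hoip* (783), *Ilk* (71.9), *Argk* (168), *mys* (18.1) and *Actn* (9.89) were above 8 RPKM in S16.

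Counts of called genes were set against other groupings of the same libraries, each in a limma fit of those libraries alone. For EC against spermatogonia, 1 of 56 groupings, the real one, gave as many genes (3158, the highest other 11). For late against EC it was 1 of 84 (5853, the highest other 643). The other groupings mix libraries of unlike stages, which raises their spread and lowers their counts. The test therefore shows that the labelled groupings gave the most genes. It cannot separate stage from a batch that follows stage. For LC2 against LC1, 1 of 10 groupings, the real one, gave as many (916, the highest other 0), and 10 groupings are too few for a share under 0.05.

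The labels give 2 LC2 libraries, and the LC2 mean holds 3. Which of them has no label is not known here. By the X ratio and by genes with a read, 0 of the 5 spermatogonial and 0 of the 6 late libraries stood apart from the rest of their group, and groups of 3 or fewer, EC among them, were not tested in this way.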
